A study of Mus musculus with 39 samples.

How the data were processed

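RNA of sorted B-lineage cells from mouse bone marrow was measured on 39 Affymetrix expression arrays. Per the labels, 6 arrays carried pro-B cells (B220+ CD43+ IgM- IgD-), 8 pre-B cells (B220+ CD43- IgM- IgD-), 6 immature B cells (IgM+ IgD-) and 3 mature B cells (IgM+ IgD+). The other 16 arrays carried leukemic pre-B cells sorted with the pre-B markers, and 5 of them came from mice that became leukemic after pIpC, a double-stranded RNA analogue that induces interferon. RNA was extracted with Trizol, 20 ng of it was amplified with the NuGEN Ovation system, and the product was biotinylated cDNA.

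The deposited values were 1 intensity per probe set and array, summarised by the authors with RMA per the submitters' processing notes, which give no version. The values were on a linear scale: array medians lay between 82.0 and 108.7 and array maxima between 15090 and 18549. They were therefore taken to log2 with no offset. The notes do not state whether all 39 arrays were normalized together, so a residual difference in scale between sets of arrays cannot be excluded from the files. Arrays have no read depth, and the number of arrays per group limits the precision.

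The table held 22690 probe sets. Of these, 64 were array controls, 691 carried several gene symbols and 1555 carried none, and all of these were left out. The remaining 20380 probe sets represented 12393 genes, of which 4956 had more than 1 probe set. Each gene was represented by its probe set with the highest mean over all 39 arrays. For 20351 of the probe sets the gene identifier was in the mouse gene reference, and 0 symbols needed an update. No genome was at hand, so no gene positions are given. A gene whose probe sets all carried several symbols, such as Dot1l, was not analysed.

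All design choices in this paragraph and in the next were made before the data were examined. Comparisons used limma 3.58.1 in R 4.3.3 on the log2 values (lmFit, then eBayes with an intensity trend), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Leukemic pre-B was compared with normal pre-B in a fit of those 24 arrays and with normal pro-B in a fit of those 22 arrays. The steps pre-B against pro-B, immature B against pre-B and mature B against immature B came from 1 fit of the 23 normal arrays. Leukemic arrays with and without pIpC in the description were compared in a fit of the 16 leukemic arrays. The labels give no separate animal for each normal array, and the leukemic titles carry different numbers, so the p-values measure the spread between these samples. Each array was also correlated across genes with the mean of each normal stage, over 5443 genes that varied between the normal stages (limma F test). A normal array was left out of its own stage mean, but not out of the choice of genes.

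Lists of genes fixed from textbook knowledge were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation. The 19 lists tested were the Hoxa cluster, MLL-fusion-associated genes, the MLL, DOT1L and elongation complex, early B and surrogate light chain genes, B-lineage transcription factors, B-cell receptor and surface genes, mature B and antigen presentation genes, cell cycle genes, stem and progenitor genes, interferon response genes, p53 target genes, the BCL2 family, glycolysis genes, immediate early and stress genes, and markers of myeloid, T and NK, erythroid, plasma and plasmacytoid dendritic cells. A list of sex-linked genes was only inspected. The genes named in the text are those with the largest differences in each direction whose groups did not overlap (up to 6 per direction, predicted genes left out; at least 90% of the leukemic arrays beyond every normal array where leukemic cells were compared), up to 4 called and 2 uncalled members of each list described, and a preset list for the leukemic comparisons. No named gene lay near background (log2 below 4.14) in both groups of its comparison.

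The accessions form 2 runs that also split the replicate numbers, of 22 and 17 arrays, with all mature B arrays in run 2. The run was taken as a possible batch that no label states, and it entered only the alternatives below, not the main comparisons. The difference between the 3' and 5' beta-actin control probe sets was 1.29 ± 0.084 (SD, log2) in run 1 and 0.80 ± 0.139 in run 2, with no overlap. The same difference for Gapdh was higher in run 2 and also varied with the groups: 0.92 in pro-B, 1.04 in pre-B, 1.10 in immature B and 0.93 in leukemic arrays of run 1, and 1.15, 1.26, 1.41 and 1.09 in run 2, with 1.59 in mature B. No comparison was adjusted for it, so an effect of RNA integrity or amplification on the differences is not excluded. Alternatives were quantile normalization, leaving out the dimmest 40% of genes, the mean of all probe sets of a gene, leaving out probe set types that match several transcripts (names ending in _x_at, _s_at or _a_at), all 39 arrays in 1 fit, no intensity trend, the run as a covariate, each run alone, a replicate block, array weights per group, and each array left out in turn. Added after the data were seen were the mean of the myeloid markers as a covariate, leaving out leukemic arrays with low Xist, leaving out leukemic arrays 122 and 226, leaving out the 4 normal arrays with high Csf1r, and, for pre-B against pro-B, the mean of the T and NK cell markers as a covariate.

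The procedure was tested on simulated data in which 200 of 12393 genes were changed. Of changes of 2 log2 units, 85% to 99% were recovered across the 6 comparisons, of changes of 1 log2 unit 53% to 78%, and at most 5.1% of the calls were false. The simulated noise was independent between genes, had the same SD in all groups of a gene, and held no run effect and no admixed cells. The real data differ in these respects, so these shares are not error rates of the real calls. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.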

Results

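Expression was measured in 4 normal stages of B-cell development in mouse bone marrow and in leukemic lymphoblasts that the series title describes as MLL-AF4. Sorting by surface markers gave 6 arrays of pro-B cells, 8 of pre-B cells, 6 of immature B cells, 3 of mature B cells and 16 of leukemic cells with the pre-B surface markers. The description of leukemic array 116 names pre-B cells of a mouse with the MLL-AF4 allele and does not state leukemia, while its label is leukemic pre-B. The array medians spanned 6.36 to 6.76 on the log2 scale. Every difference below is a difference of mean log2 intensity, and the number of arrays limits its precision.

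The MLL gene, Kmt2a in the mouse, encodes a histone methyltransferase that keeps Hoxa genes active in stem cells, and its fusion with AF4 (Aff1) is found in infant leukemia of an early B-cell type. Normal pre-B cells have rearranged the heavy chain, carry the pre-B-cell receptor and have lost Hoxa9 and Flt3. The comparison of leukemic pre-B with normal pre-B cells asked how the leukemic cells differ from normal cells of the same sort gate. It called 1987 of 12393 genes, 1054 higher and 933 lower in the leukemic cells, and 315 of the higher and 342 of the lower genes differed at least 2-fold. Within accession run 1 alone 1001 genes were called, within run 2 alone 1968, and with the run as a covariate 2756.

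Among genes with at least 90% of the leukemic arrays beyond every normal pre-B array, the largest rises were in Lhx2, Tmprss4, Ptpn22, Insm1, Asns and Hpgd. Lhx2, a LIM homeobox factor of blood stem cells, rose by 3.73, with 15 of 16 leukemic arrays above every normal pre-B array. Tmprss4, a membrane serine protease, rose by 3.68, and Ptpn22, a phosphatase that restrains antigen receptor signals, was 11.6-fold higher, both on 16 of 16 arrays. Asns makes asparagine, the amino acid that asparaginase therapy removes, and was 7.68-fold higher on 16 of 16 arrays (9.56 ± 0.87 against 6.62 ± 0.67, SD). Insm1, a zinc-finger factor, rose by 3.16 and Hpgd, which breaks down prostaglandins, by 2.84 on the log2 scale. Normal pre-B means of Lhx2, Tmprss4 and Hpgd, and below of Hoxa9, Hoxa10 and Meis1, lay under the background limit of 4.14, so the size of these rises is not resolved. The largest falls among such genes were in Steap4, Reln, Prg3, Mgst1, Slc15a2 and Gpr12. Steap4, a metalloreductase, fell by 4.41, from 9.27 ± 0.44 to 4.85 ± 1.03 (SD), and Reln, better known as a secreted protein of the brain, fell by 4.05. Prg3, an eosinophil granule protein, fell by 3.95, Gpr12, a G-protein-coupled receptor, by 3.54, Mgst1, a glutathione transferase, by 3.67 and Slc15a2, a peptide transporter, by 3.64. For Slc15a2 15 arrays lay below every normal pre-B array and for the other 5 genes all 16 did.

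Hoxa9 showed the largest rise among the preset genes. It was at 9.41 ± 2.85 on the leukemic and 4.11 ± 0.50 on the normal pre-B arrays (SD), a difference of 5.30 (SE 0.95, adjusted p = 0.000245). On 13 of 16 leukemic arrays Hoxa9 lay above every normal pre-B array, and arrays 116, 117 and 154 were the exceptions at 3.79, 4.52 and 3.24. Of the 9 Hoxa cluster genes measured, 5 rose and 4 were not called, and 6 rose when adjusted over the list alone. Hoxa10 rose by 3.99, Hoxa5 by 1.49 and Hoxa7 by 1.23. The list mean rose by 1.71 (camera adjusted p = 0.000588, p = 0.289 with an estimated correlation) and exceeded that of every normal pre-B array on 12 of 16 leukemic arrays. It rose by 1.51 within run 1, 2.07 within run 2 and 1.73 with the run as a covariate. The call of Hoxa5 was lost when any 1 of pre-B arrays 2 to 6 was left out, with differences of 1.31 to 1.49.

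Of the 20 other genes associated with MLL fusions, 5 rose, 3 fell and 12 were not called, also when adjusted over the list alone (mean 0.41, camera adjusted p = 0.324). Meis1, the homeobox partner of Hoxa9, rose (5.23 ± 1.40 against 3.19 ± 0.34, SD) and lay above every normal pre-B array on 13 of 16. Myc, which drives growth and ribosome production, rose 6.63-fold on 15 of 16 arrays (adjusted p = 2.31e-07). The cell cycle kinase Cdk6 rose by 1.72 and the survival gene Bcl2 by 1.31. The Bcl2 call was lost without any 1 of pre-B arrays 1, 2, 3, 4 or 8 or leukemic array 153, with differences of 1.25 to 1.31. Flt3, a cytokine receptor that is often high in MLL leukemia, was 1.53 higher and was not called (adjusted p = 0.182). Cdkn2a, the locus of the p16 and p19 tumour suppressors, rose 4.02-fold on 13 of 16 arrays. Kmt2a itself fell by 1.62 and Aff1 by 0.62, with 16 and 12 of 16 arrays below every normal pre-B array. The mean fall of Kmt2a was enlarged by leukemic arrays 17 and A46, which lay far below the other leukemic arrays. Where these probe sets lie in the fusion transcript is not known from the files. Of the 16 genes of the MLL, DOT1L and elongation complex, 2 rose and 2 fell, and 2 and 3 when adjusted over the list alone (mean -0.28, camera adjusted p = 0.54). Dot1l was not analysed here.

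**Figure D1:**
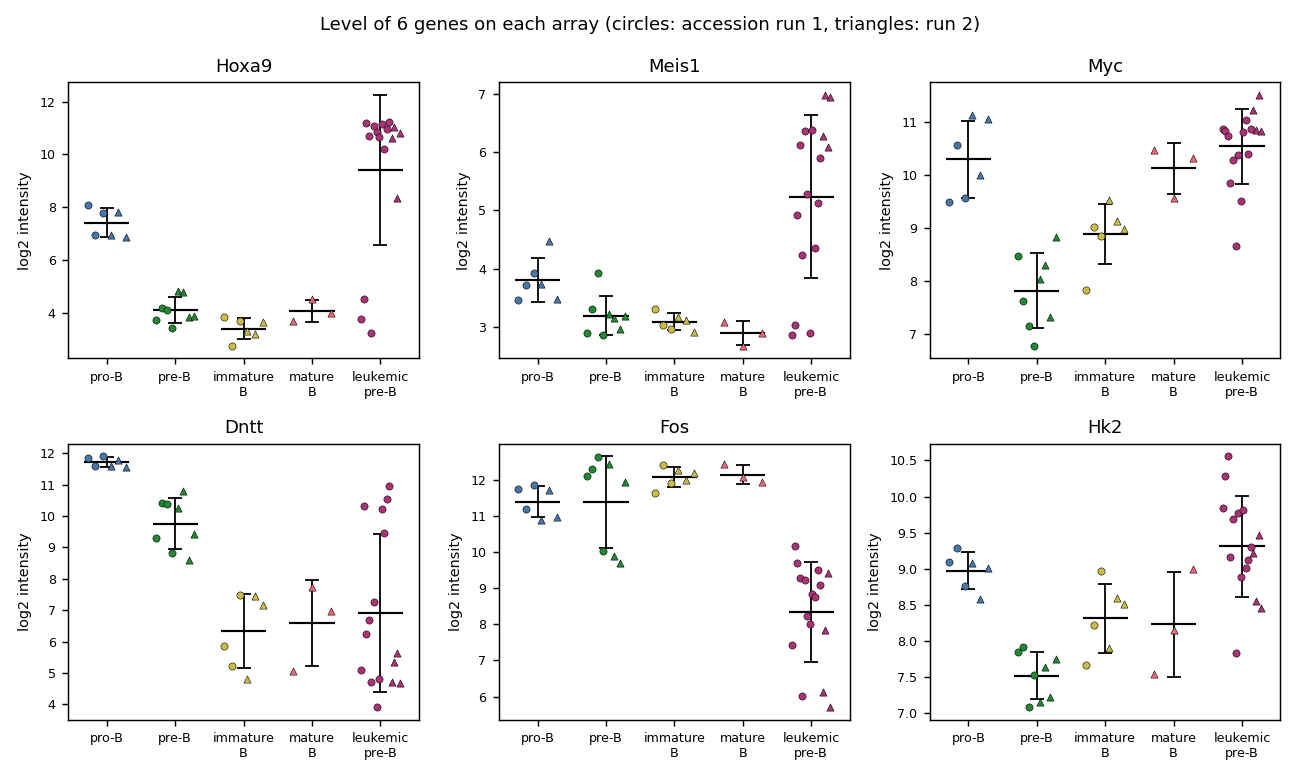
Log2 intensity of Hoxa9, Meis1, Myc, Dntt, Fos and Hk2 on each of the 39 arrays by group (circles, accession run 1; triangles, run 2; line, group mean; bars, SD). Hoxa9 lies between 8.36 and 11.24 on 13 leukemic arrays and between 3.24 and 4.52 on the other 3.

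Genes of the B-cell receptor and the B-cell surface were lower in the leukemic cells. Of 14 measured, 7 fell and 0 rose by limma, 8 fell when adjusted over the list alone, and the list mean fell by 1.18 (camera adjusted p = 8.57e-06, p = 0.0453 with an estimated correlation). All 16 leukemic arrays had a list mean below that of every normal pre-B array. The fall was 0.99 within run 1 (-0.99), 1.34 within run 2 (-1.34) and 1.13 with the run as a covariate (-1.13). Fcrla, an intracellular Fc receptor-like protein, fell by 3.02, the Src kinase Blk by 2.93 and the coreceptor Cd72 by 2.90, each on 16 of 16 arrays. The signal chain Cd79a was not called (-0.67, adjusted p = 0.315). Of 17 B-lineage transcription factors, 5 fell and 1 rose, also when adjusted over the list alone (mean -0.48, camera adjusted p = 0.00868, p = 0.424 with an estimated correlation). Their mean was -0.46 within run 1 and -0.34 within run 2, and 14 of 16 arrays lay below every normal one. Klf2, which keeps resting lymphocytes quiescent, fell by 2.72, while Bcl11a, an early lymphoid factor, rose by 1.37. The lineage factors Pax5 (-0.27) and Ebf1 (-0.46) were not called.

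Genes of the early B stages moved in both directions. Of 14 in the list, 2 rose and 4 fell, and 4 rose and 7 fell when adjusted over the list alone (mean -0.12, camera adjusted p = 0.278). The surrogate light chain gene Vpreb1 rose by 1.04 on 15 of 16 arrays, and the transcription factor gene Erg rose by 2.19. The call of Vpreb1 was lost without any 1 of pre-B arrays 1, 3, 5, 6, 7 or 8 or leukemic array 224, with differences of 0.98 to 1.05. Igll1, the other surrogate light chain gene, was 1.02 higher and not called; it was called without leukemic array 122 (1.32), and its other probe set lay 0.54 lower (-0.54). Rag1, which cuts the immunoglobulin genes, fell by 1.60 and Dntt, which adds nucleotides at the joins, by 2.84. The interleukin-7 receptor gene Il7r was not called (-0.27). Of 18 genes of mature B cells and antigen presentation, 5 fell, also when adjusted over the list alone (mean -0.55, camera adjusted p = 0.0311, p = 0.531 with an estimated correlation). The homing receptor Ccr7 fell by 2.95 and S1pr1, which lets lymphocytes leave tissues, by 2.11, each on 14 of 16 arrays. The list mean was -0.26 within run 1 and -1.25 within run 2.

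Glycolysis genes rose: 7 of 11 were called, 8 when adjusted over the list alone, and the mean rose by 0.70 (camera adjusted p = 1.15e-06, p = 0.0453 with an estimated correlation). The rise was 0.78 within run 1, 0.83 within run 2 and 0.80 with the run as a covariate, and 13 of 16 arrays lay above every normal pre-B array. Hk2, which traps glucose in the cell, rose by 1.79, Ldha, which makes lactate, by 1.08 and Pgam1 by 0.80. Immediate early and stress genes fell: 6 of 12 were called, 7 when adjusted over the list alone (mean -1.30, camera adjusted p = 8.14e-05, p = 0.303 with an estimated correlation). The AP-1 genes Jun and Fos fell by 3.44 and 3.04, each on 14 of 16 arrays, and Egr1 was not called (-0.27). The list mean was -1.40 within run 1 and -1.58 within run 2, with 11 of 16 arrays below every normal one. Of 28 cell cycle genes, 5 fell, and 11 when adjusted over the list alone (mean -0.30, camera adjusted p = 0.00044, p = 0.531 with an estimated correlation), on 6 of 16 arrays below every normal one. The proliferation marker Mki67 fell by 0.48, from 12.55 ± 0.21 to 12.07 ± 0.39 (SD). Foxm1, a factor for mitotic genes, fell by 0.73, a call lost within each run and without any 1 of pre-B arrays 1 to 4 (-0.74 to -0.66). The mean of the cell cycle list was -0.26 within run 1 and -0.09 within run 2.

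Markers of other cells also differed between these fractions. Of 16 myeloid markers 5 fell, 6 fell and 1 rose when adjusted over the list alone, and the mean fell by 1.11 (camera adjusted p = 0.00174, p = 0.522 with an estimated correlation), by similar amounts in run 1 (-1.10) and run 2 (-1.04). Camp and S100a8, granule and cytosol proteins of neutrophils, were at 10.79 ± 0.90 and 11.92 ± 0.63 on the normal pre-B arrays (SD) and fell by 3.44 and 2.77. Of 10 plasmacytoid dendritic cell markers 3 fell (mean -1.04, camera adjusted p = 0.0119), and of 9 erythroid markers 3 fell, 4 when adjusted over the list alone (mean -0.35, camera adjusted p = 0.0213). Of 16 interferon response genes 2 rose (mean 0.61, camera adjusted p = 0.0311), with a mean of 0.84 within run 1 and 0.15 within run 2. The list mean lay above every normal pre-B array on 7 of 16 leukemic arrays and below every one on 4. With the myeloid covariate the difference was 1.06, and with the run as a covariate that list was no longer called. With dim genes left out the dendritic, erythroid and interferon lists were not called, and with the myeloid mean as a covariate the dendritic and mature B lists were not called. With an estimated correlation the adjusted p of the dendritic, erythroid and interferon lists was 0.522, 0.424 and 0.6. The remaining lists were not called: T and NK cell markers (1 up, 3 down of 15; mean -0.04, adjusted p = 0.636), plasma cell markers (1 down of 7; mean -0.30, adjusted p = 0.367), the BCL2 family (2 up, 1 down of 10; mean 0.29, adjusted p = 0.614), p53 target genes (3 up, 2 down of 13; mean 0.30, adjusted p = 0.259) and stem and progenitor genes (0 of 13; mean 0.11, adjusted p = 0.696).

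Cells of the pro-B fraction have not yet completed heavy chain rearrangement, express Flt3, Kit and Dntt, and are the stage that human MLL-AF4 leukemia resembles most by surface markers. The B220+ CD43+ gate can also admit plasmacytoid dendritic cells, which carry B220, and some NK cells, which carry CD43. The comparison of leukemic pre-B with normal pro-B cells asked which differences remain against this earlier stage. It called 1950 genes, 1005 higher and 945 lower, and 95 of the higher and 684 of the lower genes differed at least 2-fold. The median difference of all genes was 0.126, and 0.019 with the dimmest 40% of genes left out, where 813 were called, 234 higher and 579 lower. Within run 1 344 genes were called, within run 2 786, and with the run as a covariate 2496. Leaving out pro-B arrays 1, 2, 3 or 6 gave 1286, 860, 1252 and 957 genes.

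Among genes with at least 90% of the leukemic arrays beyond every pro-B array, the largest falls were in Gzma, Klk1, D13Ertd608e, Ptprf, Cd209d and Klra17. Gzma, a granule protease of cytotoxic cells, fell by 6.42, Klk1, a kallikrein, by 6.33 and Cd209d, a lectin of dendritic cells, by 5.88. Klra17 (Ly49Q), a lectin-like receptor of plasmacytoid dendritic cells, fell by 5.74, Ptprf, a receptor phosphatase, by 6.05 and D13Ertd608e by 6.26, and all 6 genes lay below every pro-B array on 16 of 16 leukemic arrays. Of 15 T and NK cell markers, 11 fell, also when adjusted over the list alone (mean -2.68, camera adjusted p = 2.53e-16, p = 0.0161 with an estimated correlation), at -2.57 within run 1 and -3.19 within run 2. Ncr1, a receptor found on NK cells, fell by 4.83 and the cytotoxic granule protein Nkg7 by 4.25. Of 10 plasmacytoid dendritic cell markers, 9 fell, also when adjusted over the list alone (mean -3.67, camera adjusted p = 1.24e-14, p = 0.0161 with an estimated correlation), at -3.69 within run 1 and -3.80 within run 2. Ccr9, a homing receptor, fell by 4.47 and the inhibitory receptor Lair1 by 4.59. In both lists the mean of all 16 leukemic arrays lay below that of every pro-B array. Of 16 myeloid markers 7 fell, 12 when adjusted over the list alone (mean -2.46, camera adjusted p = 4.8e-11, p = 0.0941 with an estimated correlation), at -2.28 within run 1 and -2.55 within run 2. The neutrophil granule genes Camp and Ltf fell by 4.78 and 4.34. Of 9 erythroid markers 4 fell (mean -0.83, camera adjusted p = 1.5e-06, p = 0.0181 with an estimated correlation), among them Car1 by 2.97, and the mean of 16 of 16 arrays lay below every pro-B array. Of 7 plasma cell markers 2 fell (mean -0.92, camera adjusted p = 0.0178, p = 0.17 with an estimated correlation), on 14 of 16 arrays, at -0.73 within run 1 and -1.61 within run 2. With dim genes left out the erythroid and plasma cell lists were not called. With the mean of the myeloid markers as a covariate, an alternative chosen after the data were seen, 279 genes were called; that mean lies below every pro-B array on 15 of 16 leukemic arrays, so the covariate also removes differences between the groups.

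Among the genes higher than in pro-B cells, Hoxa10 rose by 4.31 with 15 of 16 arrays above every pro-B array, Lhx2 by 3.85, Insm1 by 3.56 and Ryr2, a calcium release channel, by 3.82. Tnnt2, a troponin, rose by 2.87 and Cth, which makes cysteine, by 2.67. Means below 4.14, where sizes are not resolved, were those of Hoxa10, Lhx2, Insm1, Cth and Cdkn2a in pro-B cells and of Gzma, Klk1, Ncr1 and Car1 in leukemic cells. Cdkn2a rose by 2.40 on 16 of 16 arrays; its call was lost without pro-B array 2 or 6, at 2.33 and 2.35. Hoxa9, at 7.41 ± 0.55 in pro-B cells (SD), was 1.99 higher in the leukemic cells and was not called (adjusted p = 0.194). Of the 9 Hoxa cluster genes 1 rose, also when adjusted over the list alone (mean 1.23, camera adjusted p = 0.0388, p = 0.443 with an estimated correlation), at 0.98 within run 1 and 1.63 within run 2, and the list was not called with the run as a covariate, after quantile normalization or with dim genes left out. Of 12 immediate early and stress genes 5 fell (mean -1.09, camera adjusted p = 1e-04, p = 0.17 with an estimated correlation), on 13 of 16 arrays below every pro-B array, at -1.10 within run 1 and -1.46 within run 2. With the myeloid marker mean as a covariate their mean was -0.56 and the list was not called. Fos fell by 3.05, Fosb by 3.46 and Jun by 2.65. Dntt fell by 4.81 on 16 of 16 arrays. Kmt2a fell by 1.42 (adjusted p = 0.0485), with leukemic arrays 17 and A46 far below the others. The call was lost without any 1 of 14 arrays, at -1.50 to -1.38. These were the 6 pro-B arrays and leukemic arrays 15, 116, 154, 224, 227, 228, 270 and A992. Lists not called here included glycolysis genes (mean 0.06, camera adjusted p = 0.769), B-cell receptor and surface genes (-0.48, 0.0509), mature B and antigen presentation genes (-0.47, 0.0509) and cell cycle genes (0.08, 0.963). With the mean of all probe sets the receptor and mature B lists were called, and with the run as a covariate the mature B list was called (-0.61). Interferon response genes were not called (-0.31, 0.148), but with the myeloid covariate their mean was 0.81 and the list was called. With that covariate glycolysis genes (0.43), B-cell receptor and surface genes (-0.57), B-lineage transcription factors (-0.41) and early B genes (-1.05) were called too. Genes not called were Myc (0.24), Flt3 (-2.33, adjusted p = 0.0599), Bcl2 (-1.05), Igll1 (-0.18), Vpreb1 (0.04), Rag1 (0.11) and Il7r (-0.05). Flt3 was called without leukemic array 117 or 122, at -2.58 and -2.65, and Bcl2 without array 122, at -1.25.

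Each array was also compared with the 4 normal stages as a whole, to ask which stage the leukemic cells lie closest to. Of 16 leukemic arrays, 13 correlated most with the pre-B mean and 3, arrays 117, 122 and 153, with the pro-B mean, across 5443 genes that vary between the normal stages. Genes are not independent replicates, so the result is a count of arrays. The pro-B arrays also had higher mean T and NK (8.286 against 5.645 in pre-B), plasmacytoid dendritic (10.214 against 7.577) and myeloid markers (9.355 against 8.007). No alternative left these markers out, so closeness to a stage was not separated from the share of other cells. All 23 normal arrays correlated most with the mean of their own stage. The genes were chosen for differences between these same normal arrays, so this match was favoured in advance. With cell cycle genes left out immature B array 4 was closer to pre-B (0.408) than to immature B (0.273). Across all genes the single closest array to immature B array 4 was mature B array 2, and to mature B arrays 2 and 3 it was immature B arrays 4 and 2. For leukemic arrays 122, 226 and 15 it was a normal array (pro-B 2, pre-B 7 and pre-B 4), and for the other 13 another leukemic array. The highest correlation of a leukemic array with the pre-B mean was 0.525 (array 228), below the 0.707 of the lowest normal pre-B array (array 4). The choice of genes favours the normal arrays in this contrast as well.

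**Figure D2:**
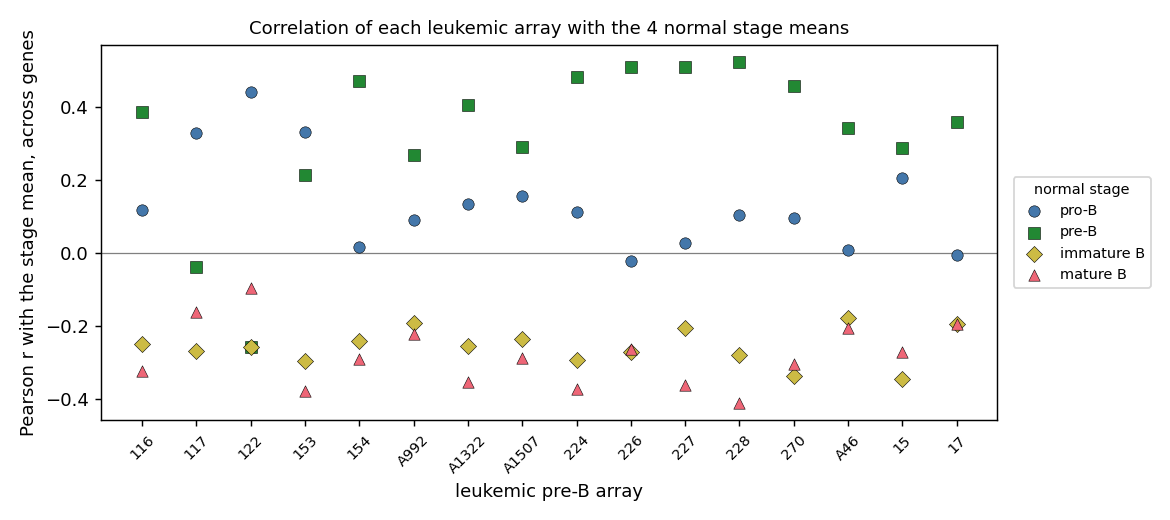
Pearson correlation across 5443 genes of each of the 16 leukemic arrays (x axis) with the means of the 4 normal stages (symbols). Arrays 117, 122 and 153 lie closest to pro-B, at 0.329, 0.442 and 0.333, and the other 13 closest to pre-B.

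The step from pro-B to pre-B follows a productive heavy chain: cells pass through a burst of division, drop Kit, Flt3 and Dntt, and prepare the light chain loci for cutting by the Rag proteins. The comparison of pre-B with pro-B asked which genes change at this step in normal marrow. It called 4162 genes, 2214 higher and 1948 lower in pre-B cells, and 360 and 908 of these differed at least 2-fold. The median difference of all genes was 0.111, and -0.019 with the dimmest 40% left out, where 2509 were called and the balance turned to 1017 higher and 1492 lower. Within run 1 2191 genes were called, within run 2 2055, and with the run as a covariate 5755. With all 39 arrays in 1 fit 2626 were called.

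Among genes whose groups did not overlap, the largest rises were in Reln (4.38), the interleukin-2 receptor chain Il2ra (from 5.78 to 9.78), the collagen gene Col5a3 (3.77), Gadd45g (3.18), Polm (3.04) and Gpr12 (3.01), all with 8 of 8 pre-B arrays above every pro-B array. Gadd45g responds to growth arrest (9.54 ± 0.28 against 6.36 ± 0.18, SD), and Polm is a polymerase that joins light chain segments. The largest falls among such genes were in Gbp8 (fell by 4.76), Ighg3 (fell by 4.46), Hs3st1 (fell by 4.24), Clec10a (fell by 4.21), Lair1 (fell by 4.19) and Fyb (fell by 4.14). Gbp8 is an interferon-induced GTPase, Clec10a a lectin of macrophages and dendritic cells, and Fyb an adaptor of T cells and myeloid cells. Lair1 is on the plasmacytoid dendritic list, and Clec10a (1.545) and Fyb (0.987) changed direction with the T and NK marker mean as a covariate. Falls in this comparison were not separated from a change in the share of other cells, whose markers also fell. Of single genes from several lists, Flt3 fell by 3.85, Kit, the stem cell factor receptor, by 2.72, Cd34 by 1.99, Hoxa9 by 3.31 and Dntt by 1.97, each on 8 of 8 arrays. Kit, Cd34 and Hoxa9 lay below 4.14 in pre-B cells and Col5a3 in pro-B cells, so the size of these changes is not resolved. Of 20 MLL-fusion-associated genes 10 fell and 4 rose, also when adjusted over the list alone (mean -0.61, camera adjusted p = 0.0053, p = 0.0997 with an estimated correlation), with 8 of 8 arrays below every pro-B array, at -0.68 within run 1 and -0.54 within run 2. Myc fell by 2.49 and Bcl2 by 2.36. Of 13 stem and progenitor genes 4 fell and 1 rose (mean -0.41, camera adjusted p = 0.0166, p = 0.112 with an estimated correlation), on 6 of 8 arrays below every pro-B array, and the list was not called with dim genes left out. The Hoxa cluster (1 of 9 down, mean -0.48, camera adjusted p = 0.151) was not called. It was called lower after quantile normalization, with the replicate block and with the myeloid covariate (mean -0.89). Early B and surrogate light chain genes were not called either, with 5 up and 5 down of 14 (mean -0.27, camera adjusted p = 0.77).

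Of 14 B-cell receptor and surface genes 9 rose and 1 fell, 10 and 1 when adjusted over the list alone (mean 0.70, camera adjusted p = 0.000177, p = 0.299 with an estimated correlation), at 0.82 within run 1 and 0.57 within run 2. The surface protein gene Ms4a1 (CD20) rose by 1.41, the signal kinase Syk by 1.33 and Blk by 1.30, and the list mean of 4 of 8 arrays exceeded that of every pro-B array. Of 17 B-lineage transcription factors 11 rose and 2 fell, also when adjusted over the list alone (mean 0.32, camera adjusted p = 0.0138, p = 0.112 with an estimated correlation), on 8 of 8 arrays, at 0.31 within run 1 and 0.33 within run 2. Bach2, a repressor that guards the pre-B checkpoint, rose by 1.48 and the E2A gene Tcf3 by 1.19, while Irf8 fell from 12.38 to 10.38. Rag1 rose by 1.71 and the costimulatory receptor Cd40 by 2.07, while of 18 mature B and antigen presentation genes 5 rose and 5 fell (mean 0.08, camera adjusted p = 0.92). Markers of other cells fell in the same comparison, as given below, and with the T and NK marker mean as a covariate Blk (-0.95) and Tcf3 (-0.04) changed direction. Of 28 cell cycle genes 4 rose, 3 when adjusted over the list alone (mean 0.39, camera adjusted p = 0.0163, p = 0.798 with an estimated correlation), with 2 of 8 arrays above every pro-B array, at 0.50 within run 1 and 0.27 within run 2. Of 11 glycolysis genes 5 fell, 7 when adjusted over the list alone (mean -0.64, camera adjusted p = 0.000138, p = 0.112 with an estimated correlation), on 7 of 8 arrays, at -0.55 within run 1 and -0.73 within run 2. Hk2 fell by 1.45.

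Of 15 T and NK cell markers 14 fell and 1 rose, also when adjusted over the list alone (mean -2.64, camera adjusted p = 9.92e-15, p = 0.0724 with an estimated correlation), at -2.67 within run 1 and -2.61 within run 2. The T-cell surface gene Thy1 fell by 3.78, and Ncr1 and Gzma fell by 4.06 each; Gzma was at 10.53 ± 0.51 in the pro-B fraction (SD). Of 10 plasmacytoid dendritic cell markers 9 fell (mean -2.64, camera adjusted p = 2.69e-09, p = 0.0997 with an estimated correlation), at -2.50 within run 1 and -2.78 within run 2. The nucleic acid sensor Tlr7 fell by 3.79 and Bst2, a tethering protein high in these cells, by 3.37. Of 16 myeloid markers 12 fell, 14 when adjusted over the list alone (mean -1.35, camera adjusted p = 2.86e-05, p = 0.298 with an estimated correlation), at -1.18 within run 1 and -1.51 within run 2. Csf1r, the receptor of monocytes and macrophages, fell by 2.63, a call lost within each run and without any 1 of pro-B arrays 1, 2, 4 or 6 or pre-B arrays 1, 6, 7 or 8 (-2.71 to -2.45). In these 3 lists the mean of all 8 pre-B arrays lay below that of every pro-B array. Of 16 interferon response genes 9 fell, 11 when adjusted over the list alone (mean -0.92, camera adjusted p = 0.000116, p = 0.298 with an estimated correlation), at -1.08 within run 1 and -0.76 within run 2, on 7 of 8 arrays. Usp18 and Mx1 fell by 2.76 and 2.45. Erythroid markers (2 of 9 down; mean -0.48, camera adjusted p = 0.151) and plasma cell markers (1 up, 2 down of 7; mean -0.62, camera adjusted p = 0.527) were not called. With the mean of the T and NK cell markers as a covariate, chosen after the data were seen, 886 genes were called; that mean lies apart between the 2 stages on every array, so the covariate also removes stage differences.

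**Figure D3:**
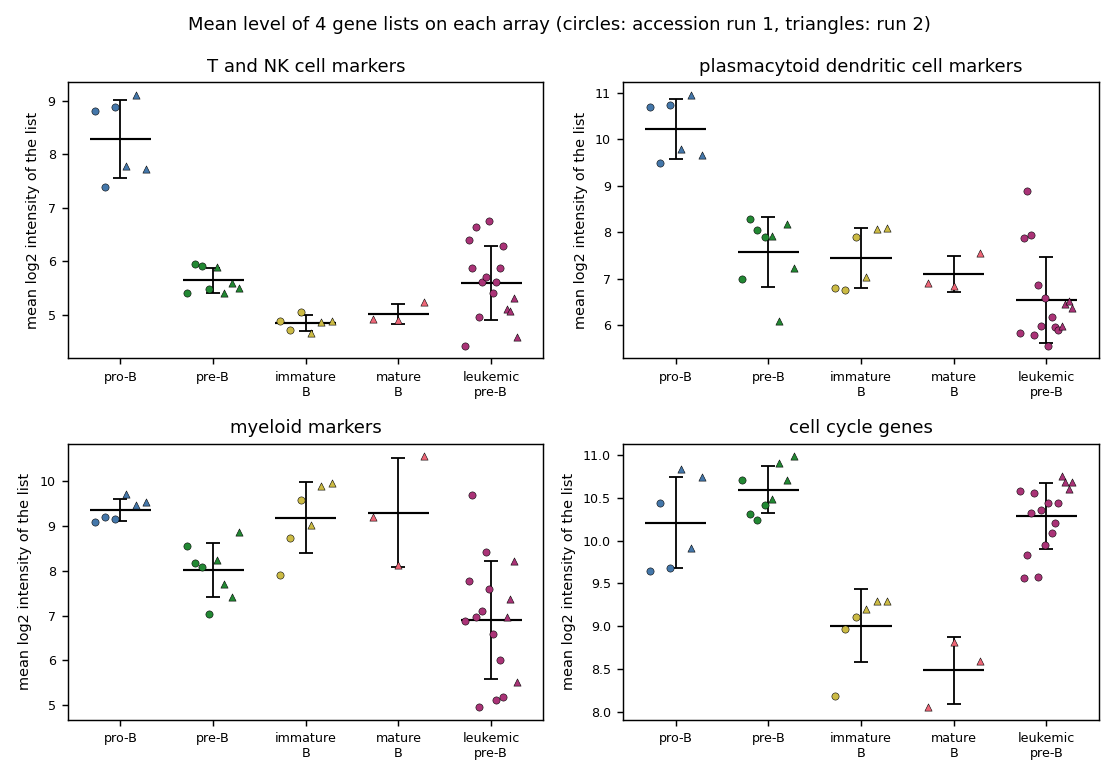
Mean log2 intensity of the T and NK cell, plasmacytoid dendritic cell and myeloid marker lists and of the cell cycle list on each of the 39 arrays by group (circles, accession run 1; triangles, run 2; line, group mean; bars, SD). The T and NK cell mean lies between 7.38 and 9.11 on the pro-B arrays and between 5.40 and 5.95 on the pre-B arrays.

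Immature B cells have assembled a light chain, carry IgM and have stopped dividing, and they shut down the recombination enzymes unless the receptor is autoreactive. The comparison of immature B with pre-B asked which genes accompany this change. It called 2426 genes, 1348 higher and 1078 lower, and 471 and 400 of these differed at least 2-fold. Within run 1 1314 genes were called, within run 2 1817, and with the run as a covariate 3501. With all 39 arrays in 1 fit 1414 were called.

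Among genes whose groups did not overlap, the largest rises were in Tlr1 (4.69), Cd83 (4.51), H2-DMb2 (3.67), Fgd2 (3.66), Igkv9-120 (3.60) and Cnr2 (3.55), all with 6 of 6 immature B arrays above every pre-B array. Tlr1 is a receptor for bacterial lipoproteins, Cd83 stabilises MHC class II on the surface, H2-DMb2 loads peptides onto it, and Cnr2 is the cannabinoid receptor of B cells. Igkv9-120, a light chain variable segment, had a difference of -0.03 on the probe set that remained when types matching several transcripts were left out. The largest falls among such genes were in Rag2 (fell by 3.94), Dntt (fell by 3.42), Rag1 (fell by 3.40), Gzma (fell by 3.27), Tnnt2 (fell by 3.14) and the actin-binding Lima1 (fell by 2.91). Gzma and Tnnt2 lay below 4.14 in immature B cells, and Cxcr5 in pre-B cells, so the size of these changes is not resolved. Of 14 early B genes 10 fell, also when adjusted over the list alone (mean -1.43, camera adjusted p = 9.21e-07, p = 0.131 with an estimated correlation), on 6 of 6 arrays, at -1.46 within run 1 and -1.41 within run 2. Igll1 fell by 2.52 on the probe set used and rose by 0.65 on the other, and both were called.

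All 28 cell cycle genes measured fell (mean -1.59, camera adjusted p = 1.16e-26, p = 0.0992 with an estimated correlation), at -1.67 within run 1 and -1.51 within run 2. The mitotic genes Ccnb2, Bub1 and Aurka fell 4.76-fold, 4.61-fold and 4.57-fold, each on 6 of 6 arrays. Of 18 genes of mature B cells and antigen presentation 17 rose, also when adjusted over the list alone (mean 2.14, camera adjusted p = 7.89e-22, p = 0.0116 with an estimated correlation), on 6 of 6 arrays, at 1.88 within run 1 and 2.41 within run 2. The follicle homing receptor Cxcr5 rose by 3.43 and the low-affinity IgE receptor Fcer2a by 3.30. Of 14 B-cell receptor and surface genes 7 rose, 9 when adjusted over the list alone (mean 0.89, camera adjusted p = 9.21e-07, p = 0.199 with an estimated correlation), at 0.96 within run 1 and 0.82 within run 2, among them Ms4a1 by 3.39 and the inhibitory coreceptor Cd22 by 2.36. Of 17 B-lineage transcription factors 7 rose and 2 fell, 8 and 2 when adjusted over the list alone (mean 0.37, camera adjusted p = 0.00298, p = 0.0992 with an estimated correlation), on 6 of 6 arrays, at 0.34 within run 1 and 0.40 within run 2, a call lost with dim genes left out. Pax5 rose by 1.15. The transcription cofactor Lmo2 rose by 2.05. Of 16 interferon response genes 10 rose, 14 when adjusted over the list alone (mean 1.25, camera adjusted p = 2.1e-08, p = 0.139 with an estimated correlation), on 5 of 6 arrays, at 1.22 within run 1 and 1.29 within run 2. Without the 3 arrays with high Csf1r described below this mean was 0.82. Mx1 rose by 2.22 and Rtp4 by 2.05.

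Of 16 myeloid markers 6 rose, 13 when adjusted over the list alone (mean 1.17, camera adjusted p = 4.61e-05, p = 0.347 with an estimated correlation), at 0.78 within run 1 and 1.57 within run 2, on 4 of 6 arrays above every pre-B array. The monocyte receptor gene Csf1r rose by 3.40, and it lay above every pre-B array on 3 of 6 immature B arrays. Lyz2, a lysozyme of the same cells, rose by 1.77. Without immature B arrays 2, 3 and 6, which had the highest Csf1r and were left out after the data were seen, neither gene was called (0.80 and 0.65), the myeloid mean was 0.55 higher and 1468 genes were called. Of the other lists called, T and NK cell markers fell (mean -0.80, camera adjusted p = 0.00298) on 6 of 6 arrays, erythroid markers rose (mean 0.91, camera adjusted p = 0.00879) on 5 of 6 and glycolysis genes rose (mean 0.31, camera adjusted p = 0.0428) on 3 of 6 arrays beyond every pre-B array. Each of these 3 had an adjusted p of 0.365 with an estimated correlation, and none of them was called with dim genes left out. The erythroid mean moved with the myeloid markers, at 0.25 without the high-Csf1r arrays and 0.01 with the myeloid mean as a covariate, where the list was not called. The glycolysis mean was 0.19 without the high-Csf1r arrays, and the list was also not called after quantile normalization, with the mean of all probe sets or with the myeloid covariate.

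Mature B cells that recirculate to the marrow carry IgD, need BAFF-driven survival and take up positions in follicles. The comparison of mature B with immature B asked which genes change at this last step. It rested on 3 mature B arrays, all in run 2, and called 651 genes, 243 higher and 408 lower, with 135 and 182 at least 2-fold. Against the 3 immature B arrays of run 2 441 genes were called, with the run as a covariate 1026, and with all 39 arrays in 1 fit 203. Without mature B array 1 or 3 the count was 241 or 364.

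Among genes whose groups did not overlap, the largest rises were in Crip3 (4.08), Crisp3 (3.32), Gimap4 (3.23), Fcer2a (3.18), Mapk12 (3.06) and Icosl (3.04), on 3 of 3 arrays above every immature B array. Fcer2a marks follicular B cells, Gimap4 is a GTPase of lymphocyte survival and Icosl is the ligand that B cells show to helper T cells. The call of Gimap4 was lost without mature B array 1 or 3, at 2.81 and 2.87. Immature B array 4 lay far below the other immature B arrays for Gimap4 (3.857 against 7.885 to 8.742) and Icosl (6.826 against 8.588 to 8.906). That array enlarges both rises. The largest falls among such genes were in Tmprss3 (fell by 3.74), Rsph1 (fell by 3.45), Egfl6 (fell by 3.16), the peptidase Enpep (fell by 2.96), Ddc (fell by 2.88) and Il2ra (fell by 2.75). Crip3 and Crisp3 lay below 4.14 in immature B cells and Egfl6 in mature B cells, so the size of these changes is not resolved. Of 18 genes of mature B cells and antigen presentation 9 rose, 13 when adjusted over the list alone (mean 1.36, camera adjusted p = 1.87e-12, p = 0.0721 with an estimated correlation), on 3 of 3 arrays, at 1.02 within run 2. The chemokine receptors Ccr6 and Cxcr5 rose by 2.94 and 2.31 and Ciita, the master regulator of MHC class II, by 2.44. Immature B array 4 also lay far below the other immature B arrays for Ccr6 (4.783 against 7.067 to 7.73), which enlarges that rise. Bcl2 rose by 1.46, a call lost without mature B array 1 (1.17).

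Of 14 early B genes 5 fell, 8 when adjusted over the list alone (mean -0.94, camera adjusted p = 1.26e-08, p = 0.0721 with an estimated correlation), on 2 of 3 arrays below every immature B array, at -1.04 within run 2 and -0.59 without the high-Csf1r arrays. Il7r fell by 2.45, Cd93, a marker of immature B cells, by 1.97 and Sox4 by 1.78. Of 28 cell cycle genes 5 fell, also when adjusted over the list alone (mean -0.52, camera adjusted p = 3.57e-07, p = 0.589 with an estimated correlation), on 1 of 3 arrays, at -0.78 within run 2. The spindle gene Tpx2 fell by 1.43 and the cyclin Ccna2 by 1.26. Of 7 plasma cell markers 2 fell, 3 when adjusted over the list alone (mean -0.99, camera adjusted p = 0.000119, p = 0.0721 with an estimated correlation), on 2 of 3 arrays, at -1.26 within run 2. Derl3 and Edem1, which dispose of misfolded secretory proteins, fell by 1.61 and 1.24. The p53 target list was lower (mean -0.24, camera adjusted p = 0.0372, p = 0.296 with an estimated correlation) on 1 of 3 arrays and was not called with the run as a covariate, after quantile normalization or with dim genes left out.

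Poly(I:C) activates the interferon-driven Mx1-Cre used in many mouse models to switch alleles on, so the comparison within the leukemic arrays asked whether leukemias that arose after pIpC differ from the others. With 5 arrays against 11, limma called 0 of 12393 genes, and 603 had an unadjusted p under 0.05. The interferon response list was not called (mean -0.07, median 0.01, camera adjusted p = 0.502), at 0.39 within run 1 and -0.75 within run 2. With the myeloid marker mean as a covariate, chosen after the data were seen, its mean was -0.52 and the list was called. Its member Ifi35 differed by 0.08 and was not called (adjusted p = 0.982). The Hoxa cluster mean was higher with pIpC (1.07, camera adjusted p = 0.000515, p = 0.576 with an estimated correlation), above every other leukemic array on 2 of 5 and above their mean on 5 of 5, at 0.72 within run 1 and 1.84 within run 2. When adjusted over the list alone 2 of the 9 Hoxa genes were called. Hoxa9 was at 10.85 ± 0.21 with pIpC and 8.75 ± 3.26 without (SD), and the 3 arrays with low Hoxa9 were all among the 11 without pIpC (adjusted p = 0.933). The myeloid marker mean was higher with pIpC (0.86, camera adjusted p = 0.0162), above the mean of the other arrays on 5 of 5 and above every one of them on 0 of 5, at 1.13 within run 1 and 0.30 within run 2, with S100a8 1.42 higher and not called. The B-lineage transcription factor mean was higher (0.31, camera adjusted p = 0.0491), above every other leukemic array on 1 of 5, and the immediate early list lower (-0.42, camera adjusted p = 0.0213), below every other on 1 of 5. Neither was called with the run as a covariate. The transcription factor list was also not called after quantile normalization or with dim genes left out. With an estimated correlation the myeloid, transcription factor and immediate early lists had an adjusted p of 0.832.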

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

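Of the tests below, the share tests for the genes lower in leukemic cells and the counts of other splits were chosen only after the results were seen. The tests on marker co-variation, on the leukemic score and on the second Hoxa9 probe set were set before their own outcomes were seen. They were set after the patterns they examine were known.

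Of 933 genes lower in leukemic than in normal pre-B cells, markers of neutrophils such as Camp and S100a8 are part, which raises the question of RNA from myeloid cells in the normal fraction. Of the 928 lower genes outside the myeloid list, 75.3% stayed called with the myeloid marker mean as a covariate, with a median difference of -0.73 against -0.763. That marker mean spanned 4.958 to 9.69 on the leukemic and 7.03 to 8.87 on the normal pre-B arrays. The covariate was thus fitted mostly on spread among leukemic arrays, so this test cannot decide about myeloid RNA in the normal fraction. With the run as a covariate 96.2% stayed, at a median of -0.741, which argues against the accession run as the whole cause. With the 6 leukemic arrays of low Xist left out 74.1% stayed, at a median of -0.776, which argues against the sex of the animals as the whole cause. The leukemic state of the cells stays open as an untested explanation.

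Markers of plasmacytoid dendritic cells and of T and NK cells were higher in the pro-B than in the pre-B fraction, and reached high levels there (Nkg7 11.31, Gzma 10.53, Bst2 11.83, Ccr9 10.96, Cd209d 10.97 in pro-B; 8.27, 6.48, 8.46, 7.76, 8.05 in pre-B). Across the 6 pro-B arrays the 9 called dendritic markers varied together at a mean r of 0.978 (median of random sets 0.138), and the 14 called T and NK markers at 0.717 (median 0.153, 95th percentile 0.53). As a hypothesis, this is consistent with a varying share of such cells in the pro-B fraction. Plasmacytoid dendritic cells carry B220 and pass a B220 gate, and a sort against a dendritic marker would remove them, while most T cells lack B220 and a strict B220 gate would remove those. The stage itself, which could raise some of these genes in pro-B cells, stays open.

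Hoxa9 lay at the level of normal pre-B cells on leukemic arrays 116, 117 and 154. A score over the genes higher in the other leukemic arrays was 1.164, 1.346 and 1.366 above the normal pre-B mean on these arrays. It was -0.315 to 0.499 on the normal pre-B arrays, which argues against cells like those making up most of the 3 samples. The description of array 116 names pre-B cells of a mouse with the MLL-AF4 allele and does not state leukemia. The score cannot tell such cells from leukemic ones. On the second Hoxa9 probe set 3 of these 3 arrays also lay below the other 13 leukemic arrays (4.38, 4.40 and 4.27 against 5.37 to 8.85), which argues against failure of 1 probe set. No biological explanation was tested.

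Other splits of the same arrays into groups of the same sizes were fitted to see how often they call as many genes. For leukemic against pre-B 1 of 100 splits, the real one, gave as many genes (1987, highest other 3). It was also 1 of 100 for leukemic against pro-B (1950, highest other 1050) and immature B against pre-B (2426, highest other 1254). For mature B against immature B it was 1 of 84 (651, highest other 191). Chance is thus an unlikely source of these counts, but so few splits cannot exclude it. For pre-B against pro-B 2 of 100 gave as many, the real one (4162) and another with 4423, so chance is not excluded there either. The split with 4423 set the 6 pro-B and 2 pre-B arrays against the other 6 pre-B arrays, so it held most of the real one. For pIpC the real grouping called 0 genes, so 100 of 100 splits had to give as many (highest other 13). That count therefore cannot decide about chance.

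Single arrays far from the rest of their group were searched among 292 groups of values. The search covered the pro-B, pre-B and immature B arrays and the leukemic arrays with pIpC. It left out the mature B arrays and the leukemic arrays without pIpC. There were 17 such values, and chance alone gives about 1 in 20, or 14.6. Of the 17, 7 lay on immature B array 4 and 7 on pre-B array 2. On immature B array 4 the levels were Cnr2 8.356 (others 9.2 to 9.675), Gimap4 3.857 (7.885 to 8.742), Icosl 6.826 (8.588 to 8.906) and Ccr6 4.783 (7.067 to 7.73), and the list means were 5.049 for the Hoxa cluster (3.779 to 4.135), 8.181 for cell cycle genes (8.964 to 9.292) and 8.078 for immediate early genes (8.981 to 9.217). On pre-B array 2 the levels were Clec10a 3.706 (5.858 to 7.641), Lair1 3.195 (4.591 to 5.708), Fyb 3.611 (5.939 to 7.78) and Rtp4 6.707 (3.52 to 4.944), and the list means were 10.311 for early B genes (9.724 to 9.988), 6.144 for interferon response genes (5.201 to 5.604) and 8.13 for plasma cell markers (8.523 to 8.852). The others were Meis1 at 3.918 on pre-B array 7 (2.862 to 3.3), Cdkn2a at 4.834 on pre-B array 4 (3.897 to 4.244) and the stem and progenitor mean at 5.598 on leukemic array A46 (6.283 to 6.544 on the other pIpC arrays). Leukemic array 226, which was not searched, had the lowest upper quartile of intensities of all arrays (348.6). Its leukemic score of 0.571 was the lowest of the leukemic arrays, and without it 2359 genes were called for leukemic against pre-B.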

How the results depend on the processing

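Chosen after the data were seen were the myeloid and the T and NK covariates and leaving out low-Xist arrays, leukemic arrays 122 and 226 or high-Csf1r arrays; the other alternatives were planned. Of the called named genes, those that kept their direction and side of the threshold in every alternative were 27 of 43 (leukemic against pre-B), 14 of 25 (leukemic against pro-B), 6 of 36 (pre-B against pro-B), 19 of 26 (immature B) and 12 of 23 (mature B). For pre-B against pro-B the T and NK covariate removed the call of 22 and reversed 7 of the 36, and each other alternative changed at most 5. In both comparisons with pro-B the marker means used as covariates separate the groups fully or nearly, so these covariates also remove group differences. The causes of the changes below were not tested, except that single runs hold fewer arrays and the dim filter fewer genes. Where 1 group lay below the background limit of 4.14, as Hoxa9 did in normal pre-B cells at 4.11, the size of the difference is not resolved.

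Counts of called genes moved by over 1.5 times as follows. Leukemic against pre-B (1987): 1001 within run 1. Leukemic against pro-B (1950): 813 with dim genes left out, 344 within run 1, 786 within run 2, 3898 with array weights, 279 with the myeloid covariate, 1009 without low-Xist arrays and 3611 without arrays 122 and 226. Pre-B against pro-B (4162): 2509 with dim genes left out, 2626 with all 39 arrays in the fit, 2191 and 2055 within runs 1 and 2, 1648 with the myeloid and 886 with the T and NK covariate. Immature B against pre-B (2426): 1414 with all 39 arrays, 1314 within run 1 and 1468 without high-Csf1r arrays. Mature B against immature B (651): 203 with all 39 arrays, 1026 with the run as a covariate and 134 without high-Csf1r arrays. For pIpC (0): 1 without shared-suffix probe sets, 59 with all 39 arrays, 1 within run 1 and 3 without low-Xist arrays. With each array left out in turn the counts were 1617 to 2359, 860 to 2777, 3190 to 4833, 2082 to 2842, 241 to 801 and 0 to 2 in the same order. Lists called with an estimated correlation numbered 2, 3, 0, 1, 0 and 0 in that order; with dim genes left out 4 were called for leukemic against pro-B and 6 for immature B, and with the myeloid covariate 7 for pIpC. Of 16 leukemic arrays 13 were closest to pre-B, and 12 by Spearman correlation.

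Directions reversed as follows. Leukemic against pre-B: Igll1 -0.539 without shared-suffix probe sets. Leukemic against pro-B, with the myeloid covariate: Flt3 0.294, Bcl2 0.832, Vpreb1 -0.791 and Rag1 -0.845; without low-Xist arrays: Vpreb1 -0.095 and Rag1 -0.006; without arrays 122 and 226: Igll1 0.146 and Il7r 0.159; within run 2 Igll1 0.063, within run 1 Rag1 -0.009, and with the mean of all probe sets Il7r 0.039. With each array left out in turn, Igll1 spanned -0.251 to 0.111 and Il7r -0.088 to 0.155 (both highest without array 122), and Vpreb1 -0.006 to 0.28 (below 0 without A992, -0.006, or pro-B 4, -0.005). Pre-B against pro-B, with the T and NK covariate: Clec10a 1.545, Fyb 0.987, Blk -0.95, Tcf3 -0.035, Tlr7 0.5, Mx1 0.589 and Csf1r 0.678; with the myeloid covariate Csf1r 0.437. Several list means also reversed with the myeloid covariate. In leukemic against pro-B, interferon response genes went from -0.31 to 0.81, where the list was called. Stem and progenitor genes went from -0.30 to 0.14 there. In pre-B against pro-B, erythroid markers went from -0.48 to 0.56 and plasma cell markers from -0.62 to 0.01. In immature B against pre-B, immediate early genes went from 0.45 to -0.09 and the Hoxa cluster from -0.27 to 0.08. Further list means that reversed are not given here. Immature B against pre-B, without shared-suffix probe sets: Igkv9-120 -0.034 and Igll1 0.649. For pIpC, Ifi35: -0.012 with quantile normalization, -0.29 within run 2, -0.08 with the myeloid covariate, and -0.059 to 0.213 with each array left out in turn (below 0 without A992 or 226).

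Replicate numbers are shared between the normal stages, and whether the arrays pair by number is unresolved. Of 15 pairs 9 had a correlation of deviations over 0.1 (range -0.673 to 0.626), and 5 arrays correlated best with their own number. The lowest values, -0.673 and -0.664, belonged to number 4, whose arrays lay in different runs, and run differences were not taken out. With the replicate number as a block, 3057, 2550 and 581 genes were called for the steps to pre-B, immature B and mature B, glycolysis was not called for immature B, p53 target genes were not called for mature B, and the Hoxa cluster was called for pre-B.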

Other observations

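No test in this part was planned; the values were looked up after the data were seen, and the genes Mpo and Xist were chosen after their values were seen.

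Transcripts of neutrophil granules were abundant in every sorted normal fraction. S100a8 was at 12.80 in pro-B, 11.92 in pre-B, 12.65 in immature B, 12.55 in mature B and 9.16 in leukemic cells, and Camp at 12.12, 10.79, 11.72, 12.26 and 7.34. Csf1r was high on immature B arrays 2, 3 and 6 (11.48, 11.41 and 11.17) and on mature B array 3 (12.0). Among the leukemic arrays it was highest on 117, 122 and 153 (12.17, 11.63 and 11.01), the arrays closest to pro-B.

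Leukemic array 122 had low Igll1 (6.66), Cd79a (6.996) and Ebf1 (7.27) and high Mpo (12.03), a granule enzyme of myeloid cells. Meis1 lay at the level of normal pre-B cells on leukemic arrays 116 (2.86), 117 (3.03) and A1507 (2.90). Kmt2a was at 6.44 on leukemic array 17 and 6.52 on A46, and at 9.55 to 10.43 on the other 14.

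Xist, the RNA that silences 1 X chromosome in females, lay below every normal array (lowest 11.614) on leukemic arrays 153, 154, A992, 270, A46 and 17, of which 3 came from mice given pIpC. Of the 5 sex-linked genes 4 were measured, with a list mean of 5.40 in leukemic and 5.06 in normal pre-B cells, and 6 of 16 leukemic arrays lay above every normal pre-B array. The list joins Xist with Y-linked genes, which differ by sex in opposite directions, so its mean cannot show the sex. The sex of the animals is not stated in the labels. Without these 6 arrays 1639 genes were called for leukemic against pre-B, 1420 of them among the 1987, and 1009 for leukemic against pro-B, 941 of them among the 1950.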
